A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

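Single-stranded DNA of 2 genotype labels, dmc1 and rtf1dmc1, was measured on 4 two-colour Agilent arrays, each comparing 0 h and 5 h in sporulation medium. Groups were taken from the genotype labels. The titles give no distinct replicate numbers, so replicates 1 and 2 are names in deposit order and pair nothing, and slide 1 and slide 2 each hold 1 array of each label. Per the labels' protocols, DNA was digested with EcoRI, single strands were bound to BND cellulose, and the eluate was labelled by random priming without denaturation.

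The deposited files are scanner output of 1 array each. The deposited intensity values are, per the file headers, processed signals of Feature Extraction 10.7.3.1, made with spatial and multiplicative detrending, no separate background subtraction and 1 linear dye factor per channel, plus unprocessed mean and local background intensity. The log10 ratio of Cy5 over Cy3, per the file headers, equals the log10 ratio of the processed signals, and was used only for that check. Other columns used from the deposited files were outlier, background and saturation flags. The genome build of the probe coordinates and any further processing are not given in the sources used here. Of 7047 names in the files, 7013 matched the R64 gene table given, which was used only for current names and for the strand and arm letters of locus tags. Of 1389 pair names checked, 1388 joined a minus-strand gene with a plus-strand gene to its right, so pair-named windows are called regions between divergent genes. 126 probes carry no name.

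Log2(Cy3/Cy5) of the processed signals was computed for 41282 nuclear probes, control and outlier spots were left out, and each array was centred on its median, with no loess, since this is an enrichment assay. The deposited median unprocessed intensity over 4 arrays ranged from 105 to 548 in Cy3 and from 102 to 335 in Cy5, against local backgrounds of 16 to 18 and 46 to 48. In Cy3, 87.3% to 96.4% of probes were well above background, and in Cy5 89.8% to 98.9%, and no probe was saturated (0). Such enrichment raises ratios only where single strands outweigh background, which the median centring takes as 0, so a change in total amount cannot be seen. Arrays of a label correlated under -0.3, and a rule fixed beforehand then turned 1 array of each label, those of slide 1.

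Probes were averaged in 1-kb bins or in windows of 1 name, with at least 2 probes on every array. Promoter windows by coordinates were not used, since no annotation of the same build was used here. limma 3.58.1 in R 4.3.3 (lmFit, eBayes) fitted a mean per label and a dye term, which is the same term as the slide, and left 1 residual degree of freedom per unit. The empirical Bayes prior had an infinite number of degrees of freedom for bins, so their p-values rest on 1 common spread, and 11.9 for windows. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The mean of both labels is a contrast of the same model. Gene lists were tested with camera (preset correlation 0.01 and estimated) and fry, where fry's smallest p over the 9 lists was 0.0646 for the mean of both labels and 0.391 for the difference. With an estimated correlation, camera rests on the 1 residual degree of freedom, so a list could hardly pass and a lost call says little. A list member was represented by its divergent window where measured and otherwise by its own. Positional classes used 1000 circular shifts within chromosomes and exact permutation over the 6 arrangements of 4 arrays, and chromosome trends 100000 resamples, all two-sided. Centromeres were placed between the last left-arm and the first right-arm gene in the files' coordinates.

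Named genes followed a rule fixed before the data were examined: the 10 windows with the largest called ratio per label, the 10 largest labelled differences of each sign without overlap where none passed, all measured known hotspots, RTF1, DMC1 and the 3 members of each other list with the largest labelled difference in the list's direction. Dubious reading frames, taken as names that the gene table does not hold, were passed over. The 12 windows of each sign on slide 1 follow a rule chosen after the values were seen. List members named for the mean of both labels and the leading hotspot regions were picked by mean ratio over all arrays, outside the fixed rule. Window and bin models were tested on simulated data with 200 changed units. In 10046 simulated bins, 1.49%, 71.6% and 100% of labelled differences of log2 1, 2 and 3 were recovered with 3 false calls, and 70.1%, 100% and 100% of such ratios for the mean of both labels with 7 false calls. In 5915 simulated windows, the shares were 13.4%, 88.1% and 100% for the difference with 5 false calls and 85.1%, 100% and 100% for the mean with 5 false calls. In 9 simulated lists of 30 windows, camera called the 1 list shifted by 1 for the difference and 0 others. These simulations drew independent noise per array and took the labels as right. In the data the slides' labelled differences ran opposite (r = -0.63 over bins), so the shares for the difference do not carry over to these arrays.

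Alternatives were normexp background correction (offset 50), loess, arrays scaled to one spread, leaving out probes not well above background, no dye and slide term, leaving out each array (with that term also left out of its models), each slide alone, single probes, 2-kb bins, an adjusted p under 0.01, windows of at least 3 probes, other class and hotspot limits and the sign turned. Normexp started from the unprocessed mean and local background intensity, so it also dropped the detrending of the processed signals. Added after seeing the data were probes flagged on no array, medians of probes, 1 mean over all 4 arrays, and RTF1 by unprocessed signals against all windows. Bins near tRNA genes and tandem or convergent intergenic regions were not analysed here. Mitochondrial probes were left out of all comparisons.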

Results

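Single-stranded DNA was mapped across the genome of the budding yeast Saccharomyces cerevisiae, strain SK1, which enters meiosis synchronously in sporulation medium. In meiosis, programmed DNA double-strand breaks are resected to single-stranded ends. A strain without DMC1, the meiotic strand exchange protein, cannot repair them, so the ends stay detectable. The dmc1 strain served as the reference, and the rtf1dmc1 strain also lacked RTF1, a subunit of the Paf1 complex that travels with RNA polymerase II. DNA taken at 0 h and at 5 h in sporulation medium was enriched for single strands on cellulose, labelled with Cy3 or Cy5 and hybridised together to a two-colour array of 41418 probes. There were 2 arrays for each genotype label, on 2 slides. The 4 arrays had 1.04%, 18.6%, 1.06% and 14.5% of probes set aside as outlier spots (labelled dmc1 replicates 1 and 2, then rtf1dmc1 replicates 1 and 2). The number of arrays limits the precision. Whether the arrays of a label came from separate cultures or from the same extracts with dyes exchanged was not settled by the labels. The p-values measure only the spread between these arrays, which may be technical. In models with the dye and slide term, this spread is the difference between arrays paired across labels and slides. Those pairs also differ in RTF1 signal (below), so the spread may hold a difference between strains.

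The RTF1 gene went against the genotype labels of slide 2. On the array labelled rtf1dmc1 replicate 1, the 7 RTF1 probes lay at a median log2 intensity of -3.95 against the array median over both dyes, and on the array labelled dmc1 replicate 1 at 0.31. On slide 2 the order was the opposite, with -4.45 on the array labelled dmc1 replicate 2 and -0.09 on the array labelled rtf1dmc1 replicate 2. In each dye, 5 of the 7 RTF1 probes were at least 3 log2 units below the array median on the array labelled rtf1dmc1 replicate 1 and on the array labelled dmc1 replicate 2, and 0 were on the other arrays. The 2 remaining RTF1 probes, at the ends of the gene's probe run, were not that dim on any array and check nothing. DMC1 was dim on all 4 arrays, at medians of -4.69, -4.14, -3.32 and -5.22 over its 6 probes (labelled dmc1 replicates 1 and 2, then rtf1dmc1 replicates 1 and 2). Among 6529 named windows, RTF1 was the 1 window dimmer by at least 3 log2 units on both of its dim arrays than on both others. Groups follow the labels throughout, and each direction between genotypes is therefore a direction between labels.

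**Figure D1:**
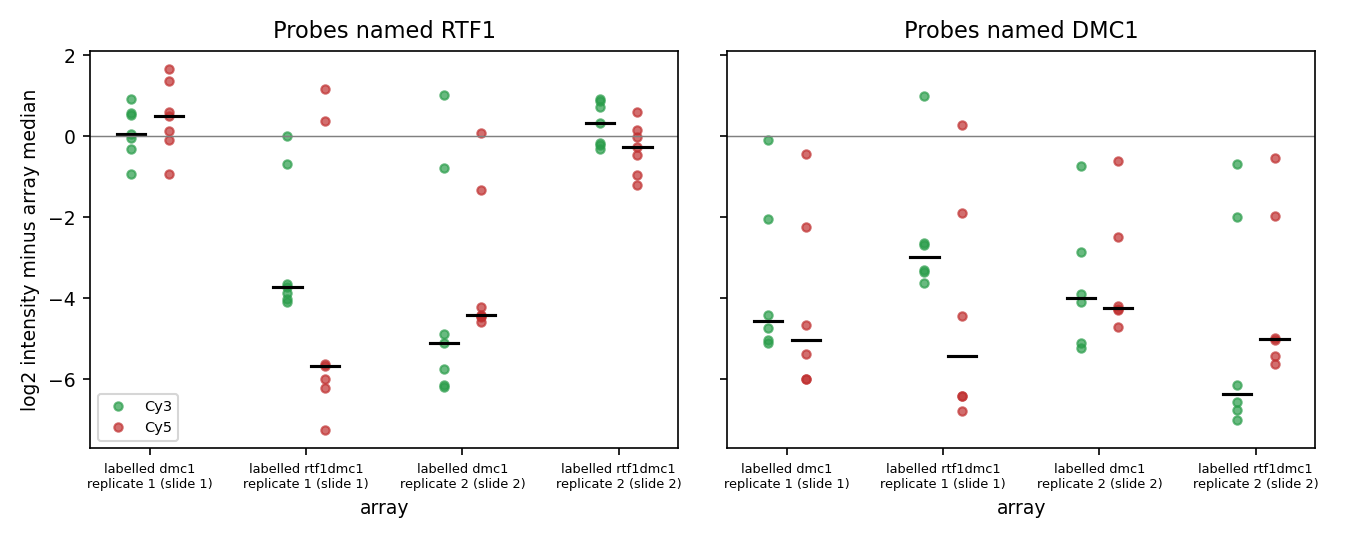
Log2 intensity minus the array median (vertical axis) of each probe named RTF1 (left) and DMC1 (right) on the 4 arrays (horizontal axis), Cy3 in green and Cy5 in red, with the median of each dye as a bar. RTF1 is dim on the array labelled rtf1dmc1 replicate 1 (median over both dyes -3.95) and on the array labelled dmc1 replicate 2 (-4.45), and near the array median on the other arrays.

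The labels put the 5 h sample in Cy3 on every array, while the design text and some titles name a dye swap. Over probes, log2(Cy3/Cy5) correlated at r = -0.49 between the arrays labelled dmc1 and at r = -0.46 between those labelled rtf1dmc1, and at 0.58 and 0.57 between the arrays of slide 1 and of slide 2. The arrays of slide 1 were therefore turned. The overall sign is not settled by the labels. It was set so that the known break hotspots were positive, which makes the values the likely ratio of 5 h over 0 h. With the sign turned, each log2 ratio of the text changes sign and "higher" and "lower" change places. The probes of known hotspots averaged log2(Cy3/Cy5) of -1.33 and -0.82 on the slide 1 arrays labelled dmc1 and rtf1dmc1, and 0.79 and 1.00 on those of slide 2.

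The comparison of 5 h with 0 h asks where single-stranded DNA accumulated in meiosis. The largest log2 ratio, likely 5 h over 0 h, was 2.66 ± 0.75 (SD, n = 4 arrays of both labels) between SND1 and CCT6, which encodes a subunit of the cytosolic chaperonin (chromosome 4, 835502 to 836360). YAT1, a carnitine acetyltransferase (chromosome 1, 189845 to 192240), stood at 2.45 ± 0.41. The region between BAP3, an amino acid permease, and HEM12, an enzyme of haem synthesis (chromosome 4, 550608 to 551757), followed at 2.44 ± 0.39, with the region between FRS2 and GAT1, a regulator of nitrogen catabolism (chromosome 6, 95098 to 95832), at 2.41 ± 0.88. SCS3, a gene of lipid metabolism (chromosome 7, 271082 to 272092), stood at 2.36 ± 0.89 and WHI5, a repressor of the start of the cell cycle (chromosome 15, 479623 to 480433), at 2.31 ± 0.30. Coordinates are those of the files, whose genome build is not given in the sources used here.

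The 10 windows with the largest called ratio were taken for each label, which gave 16 windows, 4 of them in both lists. Their means over the 4 arrays ranged from 1.96 to 2.66, and no array was below 1.31 in any of them. limma's adjusted p for the mean of both labels lay between 0.000116 and 0.000349. Besides those above they were TMA46 (2.25 ± 0.53), TPC1, a mitochondrial thiamine pyrophosphate carrier (2.22 ± 0.72), EST3/FAA3 (1.96 ± 0.58), BUD23/ARE1 (2.05 ± 0.70), YMR265C/RSN1 (2.37 ± 0.94), LPX1, a peroxisomal lipase (2.27 ± 0.17), VVS1 (2.22 ± 0.33), TGL5/WHI5 (2.13 ± 0.31), YGL007C-A/YGL006W-A (2.16 ± 0.17) and ESS1, a prolyl isomerase (2.24 ± 0.41). EST3/FAA3, BUD23/ARE1 and YMR265C/RSN1 had fewer than 2 probes well above background on at least 1 array, so their ratios are less certain. With normexp background correction of the unprocessed signals, which also drops the detrending, all 16 lost the call (limma adjusted p from 0.380 to 0.403). YMR265C/RSN1 then stood at 0.66, while the others ranged from 1.45 at EST3/FAA3 to 2.53 at SND1/CCT6. A name with a slash is the region between 2 divergent genes. WHI5, TGL5/WHI5 and LPX1 are neighbouring windows on chromosome 15, so they are not separate sites.

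Of 10046 bins of 1 kb, limma called 533 higher and 57 lower at likely 5 h on the arrays labelled dmc1, and 456 higher and 127 lower on those labelled rtf1dmc1. Without dim probes it called 440 higher and 42 lower, and 372 higher and 37 lower, and of 51 lower windows on the arrays labelled rtf1dmc1 only 12 had at least 2 probes well above background on every array. For the mean of both labels, whose ratio, though not its p, stays the same if the labels of a slide are exchanged, it called 1218 higher and 441 lower. Of 5915 named windows, 692 were higher and 103 lower for that mean, but only 54 of those 103 lower windows had at least 2 probes well above background on every array, against 622 of the 692 higher. With normexp background correction limma called 0 windows (729 at an unadjusted p under 0.05), 124 bins higher and 0 lower for that mean. Fits of 3 arrays could not keep the dye and slide term, so leaving out an array changed both. Without that term alone, the bin counts were 1887 for both labels, 419 for dmc1 and 433 for rtf1dmc1. The bin count for both labels, 1659, was 2908 without that term and the array labelled dmc1 replicate 2, 1049 without rtf1dmc1 replicate 2 and 1094 without dmc1 replicate 1. For the arrays labelled dmc1 (590) it was 136 without replicate 1, 1336 without replicate 2, and 1061 and 1116 without replicates 1 and 2 of the other label. For those labelled rtf1dmc1 (583) it was 257 without replicate 2, and 1055 and 1142 without replicates 1 and 2 of the other label.

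**Figure D2:**
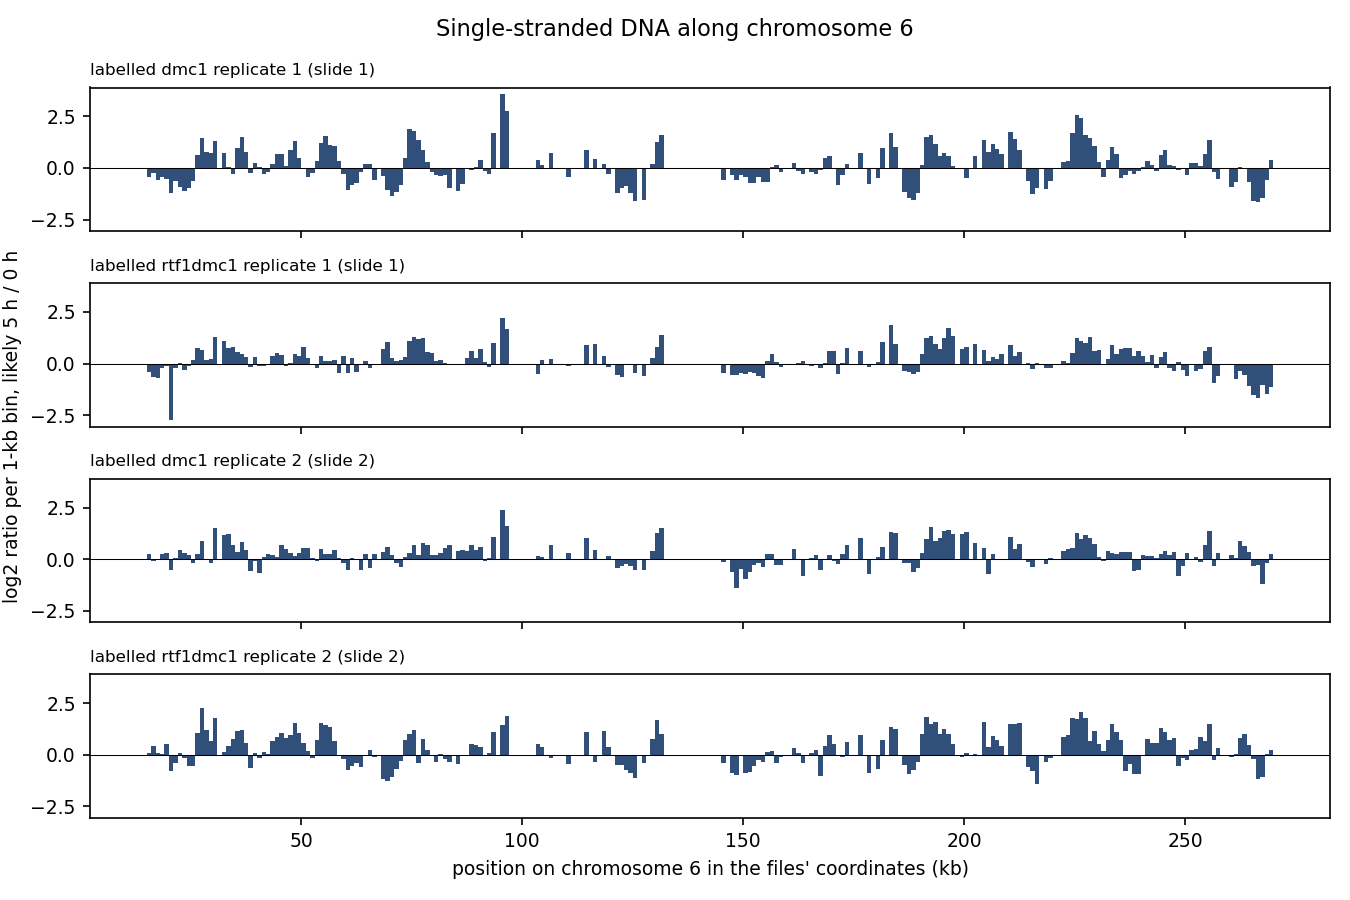
Log2 ratio (vertical axis, likely 5 h over 0 h) of each measured 1-kb bin along chromosome 6 (horizontal axis, kb in the files' coordinates) on the 4 arrays, 1 panel per array, with unmeasured bins left blank. The bins at GAT1 are the highest on the array labelled dmc1 replicate 1, where the FRS2/GAT1 window stood at 3.58, against 2.21 on the array labelled rtf1dmc1 replicate 1.

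Known break hotspots set the sign of all ratios, so the direction of this list as a whole was fixed and is no finding. Its camera call did not hold with an estimated correlation (limma adjusted p = 0.614), and fry gave limma p = 0.0881. The estimated setting, with 1 residual degree of freedom, could hardly call any list. Of the 12 windows measured for the list, 6 were called higher and 0 lower for the mean of both labels, and 8 were higher when adjusted over the list alone. The called windows were SND1/CCT6, FRS2/GAT1 and BUD23/ARE1 (above), DED81, an asparaginyl-tRNA synthetase (1.50 ± 0.27, limma adjusted p = 0.000846), CYS3, of cysteine synthesis (1.38 ± 0.83, limma adjusted p = 0.00625), and ATG23/IMD3 (1.00 ± 0.60, limma adjusted p = 0.0191). All 6 lost the call with normexp background correction (limma adjusted p from 0.380 to 0.408), at ratios of 2.53 for SND1/CCT6, 2.30 for FRS2/GAT1, 1.66 for BUD23/ARE1, 1.48 for DED81, 1.33 for CYS3 and 0.72 for ATG23/IMD3. ARG4, the arginine gene with a classic hotspot in its promoter, stood at 0.66 ± 0.48 (limma adjusted p = 0.0908) and HIS2 at 0.67 ± 0.51 (limma adjusted p = 0.0902), and neither passed. The 6 windows of the list not called were all of single genes (ARG4: chromosome 8, 139948 to 141877). All 4 windows between divergent genes were called. A single-gene window averages all probes of its name, so it does not measure a promoter alone. ARG4 passed with loess, with scaled arrays, without dim probes and without the dye and slide term (limma adjusted p = 0.0496, 0.0330, 0.00431 and 0.0488), and HIS2 with scaled arrays, without dim probes and with medians of probes (0.0334, 0.0318 and 0.0344). In fits of 3 arrays, which also lacked the dye and slide term, both passed without the array labelled dmc1 replicate 2 (0.92 and 0.94) and without rtf1dmc1 replicate 1 (0.81 and 0.81), and stood at 0.41 and 0.40 without dmc1 replicate 1. ATG23/IMD3 stood at 0.66 without rtf1dmc1 replicate 2 and did not pass (limma adjusted p = 0.0710). PES4 (0.42 ± 0.67; 0.78 and past the threshold without dmc1 replicate 1), BIK1 (0.38 ± 0.10), HIS4 (0.06 ± 0.34) and THR4 (-0.18 ± 0.56) did not pass, all as SD over 4 arrays. ERG1 had too few probes in its window, though the 6 probes that name it averaged 1.46 and 1.09 on the arrays labelled dmc1 and 1.20 and 1.88 on those labelled rtf1dmc1.

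Among the other 8 lists, amino acid biosynthesis genes had 17 of 61 windows called higher and 0 lower for the mean of both labels (22 higher and 1 lower adjusted over the list alone), with LEU4/MET4 at 1.87 ± 0.79 (SD, n = 4 arrays) and ILV5/ATG33, with fewer than 2 probes well above background on at least 1 array, at 1.63 ± 0.53. Respiration and gluconeogenesis genes had 7 of 34 higher and 0 lower (10 higher adjusted over the list alone), led by QCR2, a subunit of respiratory complex III, at 1.74 ± 0.95, and KEL3/FUM1, with fewer than 2 such probes on at least 1 array, at 1.69 ± 0.89. Glycolysis and fermentation genes had 6 of 22 higher and 1 lower (9 and 1 adjusted over the list alone), with GLK1, a glucokinase, at 1.31 ± 0.50 and CYC3/CDC19 at 1.31 ± 0.21. Subtelomeric PAU and COS genes had 0 higher and 7 of 14 lower (7 adjusted over the list alone). These near-identical copies can share signal, and PAU15, PAU20 and COS6/YRF1-3 had fewer than 2 probes well above background on at least 1 array, so the list is uncertain. These 4 lists and the known hotspots were past the threshold in limma's camera with preset correlation 0.01 (adjusted p = 3.2e-05 for known hotspots, 0.00229 for amino acid biosynthesis, 0.0230 for respiration, 0.0344 for glycolysis and 2.9e-05 for the subtelomeric families). None held with a correlation estimated from the arrays, where limma's adjusted p = 0.614 for each of the 5. With 1 residual degree of freedom that setting could hardly call any list, so it decides nothing about these 5. Over all windows, 692 of 5915 were called higher and 103 lower. Regions between divergent genes, where ratios were higher (below), stood for members where measured. They were 18 of 61 windows in amino acid biosynthesis, 12 of 34 in respiration and 8 of 22 in glycolysis. Among the 5378 windows ranked below they were 600, so that rule may raise these counts and calls.

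Meiotic genes had 3 of 29 windows higher and 0 lower (4 higher adjusted over the list alone), with REC107 at 1.35 ± 0.49 (SD, n = 4 arrays) and MIG1/HOP2 at 1.09 ± 0.09. Ribosomal protein genes had 6 of 116 higher and 0 lower (2 higher adjusted over the list alone), with RPL15B/NCW1 at 1.55 ± 0.62. Heat shock and stress genes had 6 of 26 higher and 0 lower (7 higher adjusted over the list alone), with SOD2, the mitochondrial superoxide dismutase, at 1.45 ± 0.31 and TPS1, of trehalose synthesis, at 1.15 ± 0.37. Histone genes had 1 of 4 higher, HHO1 at 0.93 ± 0.62, and 0 lower (2 higher adjusted over the list alone). Camera called none of these 4 lists (limma adjusted p from 0.0767 to 0.643). For the arrays labelled dmc1, camera called 5 lists, 3 with normexp background correction and 2 without replicate 1. None of the 5 held with an estimated correlation (limma adjusted p = 0.587 for each), a setting that could hardly call any list.

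By position in genes, ratios were highest in the regions between divergent genes, where promoters lie. The 3906 probes there averaged 0.43 ± 0.25 (SD, n = 4 arrays), and 0.74 and 0.20 on the arrays labelled dmc1 and 0.27 and 0.50 on those labelled rtf1dmc1 (replicates 1 and 2). Within genes, the 13443 probes before the midpoint averaged 0.07 ± 0.04 and the 14758 probes after it -0.10 ± 0.10. Against all other probes, the regions between divergent genes were higher by 0.39 ± 0.24, with p = 0.001 by circular-shift permutation, the smallest that 1000 shifts can give (0.00133 adjusted over 4 classes). With normexp background correction the difference was 0.23. Bins within 10 kb of centromeres lay 0.29 ± 0.06 below all others (difference -0.29, permutation p = 0.001 over 290 bins), and bins within 20 kb of chromosome ends 0.53 ± 0.28 below (difference -0.53, permutation p = 0.001 over 421 bins). Within 20 kb of centromeres and 50 kb of ends the differences were -0.16 and -0.13. In camera neither class held with an estimated correlation (limma p = 0.0727 and 0.0765), which with 1 residual degree of freedom has little power. The 89 bins within 50 kb of the ribosomal DNA, at -0.21 ± 0.08, did not pass (permutation p = 0.071).

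**Figure D3:**
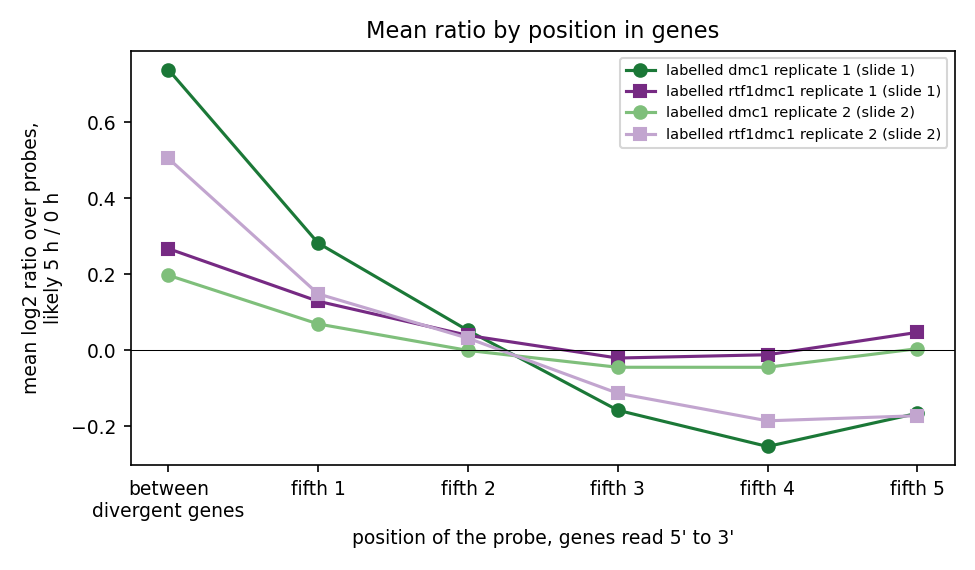
Mean log2 ratio (vertical axis, likely 5 h over 0 h) over probes between divergent genes and in each of 5 equal parts of genes read from start to end (horizontal axis), 1 line per array, green for arrays labelled dmc1 and purple for arrays labelled rtf1dmc1. Between divergent genes, the arrays labelled dmc1 replicate 1 and rtf1dmc1 replicate 2 stand at 0.74 and 0.50, and those labelled rtf1dmc1 replicate 1 and dmc1 replicate 2 at 0.27 and 0.20.

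The comparison of rtf1dmc1 with dmc1 asks how loss of RTF1 changes where breaks form. By the RTF1 probes, each label held 1 array with RTF1 dim and 1 without. Differences by label over both slides, here and below, therefore do not measure the effect of losing RTF1. Arrays were grouped by RTF1 signal only after the values were seen. So grouped, limma called 1432 bins with the dye and slide term, where the labelled difference is the spread, and 0 without it. By label, limma called 0 of 10046 bins and 0 of 5915 windows, with 66 bins and 31 windows at an unadjusted p under 0.05. Without the dye and slide term and the array labelled rtf1dmc1 replicate 2 it called 27 bins and 14 windows, and without that term and the array labelled dmc1 replicate 1 it called 1 bin, but the labelled difference is then mixed with the slide. Of 5890 windows, 13.5% had both arrays of one label above both of the other, where chance gives 33.3%. Among these, the 10 with the largest labelled difference above 0, none past the threshold, ran from 0.59 to 0.93. They were TDH2, a glyceraldehyde-3-phosphate dehydrogenase (0.93), AOS1 (0.83), ACM1 (0.74), KOG1/IKI1 (0.72), YNR068C (0.68), CMR2/ARF3 (0.63), BNA6 (0.63), CDC73/YLR419W (0.60), RBH2 (0.60) and NDD1/NUD1 (0.59). Of these, TDH2, KOG1/IKI1, CMR2/ARF3, BNA6 and CDC73/YLR419W had fewer than 2 probes well above background on at least 1 array. The 10 with the largest labelled difference below 0, ARR2, PAU15, ARR3, PRM8, HXT7, YIR042C, FDH1/YOR389W, EHD3/KRS1, YER188C-A and ARR1, ran from -1.89 to -1.33, were not past the threshold either, and all had fewer than 2 probes well above background on every array. Only relative distributions were compared, since each array was centred.

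Within slides, the labelled difference took opposite signs. The windows named next were chosen after their values were seen, as the 12 largest of each sign on slide 1 with at least 2 probes well above background on every array. Each slide gives 1 array against 1, with no replicate check. On slide 1, whose labels RTF1 did not go against, the array labelled rtf1dmc1 was lower than that labelled dmc1 by the most between YDL144C and CCT4 (log2 difference -2.51) and between MIP1, the mitochondrial DNA polymerase, and VMA4, a subunit of the vacuolar ATPase (-2.41). On slide 2 the labelled differences there were 2.12 and 1.59. YDL144C (-2.23), VMA4 (-2.12), DEP1 (-2.04), ISA1 (-2.03), YDL086W (-1.98), DPM1 (-1.98), RAD14/ERG2 (-1.97), YAP1801/MPC2 (-1.95), SDH1/AVT3 (-1.88) and SCS3 (-1.85) were next on slide 1, and DPM1, of protein glycosylation, had 2.02 on slide 2. The array labelled rtf1dmc1 was higher on slide 1 at PAU7 (1.99), VAC17 (1.79), HIR3, a histone chaperone subunit (1.56), YGL262W (1.54), CHA1, a serine deaminase (1.46), ROG3 (1.46), YNR064C (1.46), GND1, of the pentose phosphate pathway (1.45), TOR2, a growth kinase (1.42), VTH2 (1.40), DYN1, the dynein heavy chain (1.38), and HOM6 (1.36). On slide 2, all 12 of the lower windows were higher and all 12 of the higher windows were lower by label, at medians of 1.49 and -0.90. Some of these are neighbours and not separate sites (YDL144C/CCT4 and YDL144C, MIP1/VMA4 and VMA4, HIR3 and HOM6, VAC17 and CHA1). The median of the mean log2 ratio over all arrays was 1.29 in the lower windows and -0.09 in the higher ones. Of the 100 largest of each sign on slide 1, 98 lower and 95 higher windows had the opposite sign on slide 2, against 4118 of all 5378 windows ranked. Among them 39 and 0 were regions between divergent genes, which were 600 of the 5378 windows ranked.

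**Figure D4:**
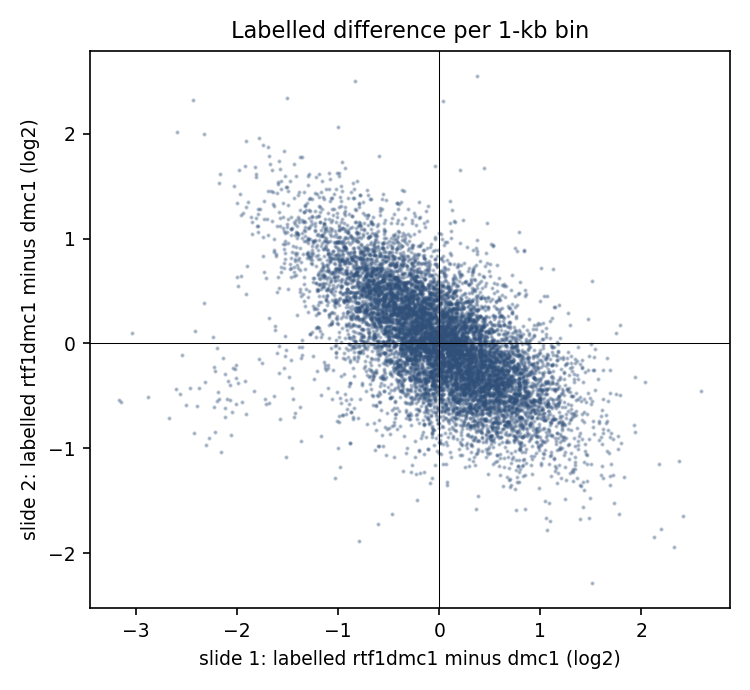
Labelled difference, rtf1dmc1 minus dmc1, in log2 ratio per 1-kb bin on slide 1 (horizontal axis) and slide 2 (vertical axis), 1 point per bin. Over 10046 bins the slides correlated at r = -0.63.

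Known hotspots had the same reversal at most sites. CYS3 differed by -1.22 on slide 1 and 1.51 on slide 2, SND1/CCT6 by -1.26 and 0.90, ATG23/IMD3 by -0.89 and 1.01, HIS2 by -0.65 and 1.00, ARG4 by -0.75 and 0.84 and DED81 by -0.64 and 0.15. PES4, a neighbour of ROG3 in the files, differed by 0.98 and -1.22, HIS4 by 0.67 and -0.19 and THR4 by 0.05 and -0.11. FRS2/GAT1 (-1.37 and -0.93) and BUD23/ARE1 (-1.08 and -0.46) were lower by label on both slides, and BIK1 (0.14 and 0.09) was higher on both. Camera called 1 of 9 lists for the labelled difference, the uncertain subtelomeric PAU and COS families (limma adjusted p = 3.3e-05). The call did not hold with an estimated correlation (limma adjusted p = 0.892), a setting with little power here. It was also lost without dim probes, where 0 lists were called. With normexp 3 lists were called, and leaving out 1 array gave 3 without dmc1 replicate 2, 2 without rtf1dmc1 replicate 2 and 0 without rtf1dmc1 replicate 1. No list had a window past the threshold for the difference, over all windows or adjusted over the list alone (0 of either). On slide 1, the median difference of glycolysis genes, 0.05, stood at percentile 99.9 of 10000 random lists matched on mean ratio, as a description of those 2 arrays. That of respiration genes, -0.51, stood at percentile 1.0 and that of meiotic genes, -0.25, at percentile 2.86. On slide 2 the medians of glycolysis, respiration and meiotic genes, 0.02, 0.29 and 0.13, stood at percentiles 3.19, 76.3 and 89.2. On slides 1 and 2, stress genes stood at percentiles 96.4 and 5.36, the subtelomeric families at 6.43 and 3.77 and ribosomal protein genes at 5.64 and 90.4. Known hotspots stood at 22.3 and 5.73, amino acid biosynthesis genes at 45.95 and 37.2 and histone genes at 47.85 and 61.4. Camera's direction for the labelled difference was down for all 9 lists, 8 of them not called (limma adjusted p from 0.303 to 0.768). The medians differed in sign from it for glycolysis genes on both slides, and on slide 2 for every list but the subtelomeric families. The members with the largest labelled differences in camera's direction were MEI4 (-0.39), NDT80 (-0.28) and MSH4 (-0.24) among meiotic genes, NAT3/RPS23B (-0.93), RPL26A (-0.63) and RPL36A (-0.50) among ribosomal protein genes, and ILV5/ATG33 (-0.77), ARO3 (-0.50) and LEU4/MET4 (-0.41) in amino acid biosynthesis. They were ADH1/PHM7 (-0.54), PFK2/YMR206W (-0.47) and CYC3/CDC19 (-0.24) in glycolysis, HHO1 (-0.27) and HTB1/HTA1 (-0.07) among histones, SSB1 (-0.54), SOD1 (-0.47) and MDJ1/HSP12 (-0.44) in stress, COX6 (-0.37), LSC1 (-0.32) and QCR7 (-0.30) in respiration, and PAU15 (-1.64), PAU20 (-0.81) and COS6/YRF1-3 (-0.79) in the subtelomeric families, none past the threshold.

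Hotspot regions, runs of 1-kb bins called higher with a mean log2 ratio of at least 1, numbered 357. DUR1,2, which encodes urea amidolyase (chromosome 2, 642001 to 643000), led them at 2.52 ± 0.65 (SD, n = 4 arrays), before YAT1 (chromosome 1, 190001 to 191000) at 2.39 ± 0.46 and PDR11/TIR3 with TIR3 (chromosome 9, 333001 to 334000) at 2.30 ± 0.68. The regions' median was 1.76 and 1.01 on the arrays labelled dmc1 and 1.03 and 1.51 on those labelled rtf1dmc1. By label, the median ratio of rtf1dmc1 over dmc1 was 0.928 and the major-axis slope 0.879, and the arrays' means over regions differed by -0.10 (exact permutation p = 1 over 6 arrangements, smallest possible 0.33). The median ratio was 1.16 without the array labelled dmc1 replicate 1, 1.21 without rtf1dmc1 replicate 1 and 0.686 without dmc1 replicate 2. With normexp background correction it was 1.31 over 90 regions. Within slides it was 0.595 on slide 1 and 1.48 on slide 2, with slopes of 0.211 and 2.69, and the array labelled rtf1dmc1 was the lower in 312 regions on slide 1 and in 63 on slide 2. Both arrays labelled rtf1dmc1 were below both labelled dmc1 in 17 regions and above in 7, where chance gives 59.5 for each.

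Arrays of the same label were not the most alike. Across bins, which are not independent replicates, Pearson's r was 0.60 between the arrays labelled dmc1 and 0.57 between those labelled rtf1dmc1. It was 0.85 between the arrays labelled dmc1 replicate 1 and rtf1dmc1 replicate 2 and 0.65 between those labelled rtf1dmc1 replicate 1 and dmc1 replicate 2, and 0.62 and 0.68 within slides 1 and 2. Spearman's correlations were 0.54, 0.51, 0.83, 0.58, 0.59 and 0.64 in the same order.

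By region, the labelled difference between divergent genes and other probes was -0.08 (exact permutation p = 1), made of -0.48 on slide 1 and 0.31 on slide 2. Chromosome ends differed by -0.13 (exact permutation p = 0.667), with -0.08 and -0.18 on the slides, and by 0.022 without dim probes and 0.062 within 50 kb of ends. Centromere regions differed by -0.07 (exact permutation p = 0.33, the smallest possible), with -0.07 and -0.08, and the ribosomal DNA flanks by 0.03 (exact permutation p = 0.667), with 0.17 and -0.10. The centromere difference was larger in size with normexp background correction (below). By circular shift of the signals with all probes, which leaves out the spread between arrays, the permutation p of the labelled difference adjusted over the 4 classes was 0.002 between divergent genes and at chromosome ends, 0.028 near centromeres and 0.9 near the ribosomal DNA. Among the 16 chromosomes, chromosome 1 (0.24 ± 0.08, SD, n = 4 arrays) and chromosome 6 (0.21 ± 0.08) had the highest mean ratio, and chromosome 9 (-0.09 ± 0.02) the lowest. The mean ratio over all arrays did not follow chromosome length (r = -0.20, permutation p = 0.455; rho = -0.12, permutation p = 0.656). Without chromosomes 4 and 1, r was 0.09. The labelled difference had r = -0.48 (permutation p = 0.0617, adjusted 0.185 over 6 relations) and rho = -0.55 (permutation p = 0.0308, adjusted 0.0925), and r = -0.36 without chromosomes 4 and 1. On slide 1 it had r = -0.64 (permutation p = 0.00778, adjusted 0.0467) and rho = -0.64 (permutation p = 0.0102, adjusted 0.0610). On slide 2 it had r = 0.27 (permutation p = 0.315) and rho = 0.31 (permutation p = 0.249), so the slides differed in sign. For the labelled difference, r was -0.55 with normexp (permutation p = 0.0277), -0.53 with loess (permutation p = 0.0331), -0.49 without dim probes (permutation p = 0.0502) and -0.18 with arrays scaled to one spread (permutation p = 0.504). With 1 array left out, which mixes it with the slide, r was 0.54 without dmc1 replicate 1 (permutation p = 0.0304), -0.70 without dmc1 replicate 2 (permutation p = 0.0025), -0.44 without rtf1dmc1 replicate 1 and -0.21 without rtf1dmc1 replicate 2.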

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

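Of the tests in this part, those of exchanged labels, dye bias, spots near background, array position, the pairing across labels and mitochondrial dye bias were chosen only after the result was seen.

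The difference between the labels rtf1dmc1 and dmc1 turned over between the slides, with r = -0.63 across bins. The tables argue against dye bias and spots near background, since r stayed at -0.55 with loess and at -0.78 without dim probes. Array position on the slide also parts the arrays this way, but RTF1 alone of 6529 windows lost at least 3 log2 units on those arrays in processed signals, which are inexact near background (smallest loss 4.58 in the median over probes of each probe's mean over both dyes, next largest window YIP4 at 1.60), and with unprocessed signals RTF1 still lost most, by 1.83 against 1.04 for YIP4. A candidate explanation is that the genotype labels of slide 2 were exchanged: RTF1 stood at -4.45 on the array labelled dmc1 replicate 2 and at -0.09 on its partner (-0.996 and 0.16 with unprocessed signals). DMC1, absent by label from every strain, was dim on both (-4.14 and -5.22). RTF1 signal near the array median on the array labelled rtf1dmc1 replicate 2 argues against the slide 2 labels as given. Where an exchange arose was not tested. With the dye and slide term, limma called 1432 bins (3634 at unadjusted p under 0.05) when arrays were paired across labels and slides, against 0 (66) by label, but the spread of each of these fits is the contrast of the other, so the counts restate the r above, and without the term both gave 0 (2691 and 67).

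Hotspot ratios were smaller on the slide 1 array labelled rtf1dmc1 than on the one labelled dmc1. Compression by background signal is argued against by brightness: the ratio of the arrays' median hotspot values was 0.537 in the brightest of 3 groups of hotspot probes (bootstrap interval over probes 0.505 to 0.572) and 0.628 in the dimmest. Array scale alone is argued against, since what was left of each slide after regressing one array on the other correlated at r = -0.45 across bins. On both slides the array where RTF1 was dim had the lower median over hotspot regions. These medians were 1.03 (labelled rtf1dmc1 replicate 1) and 1.01 (labelled dmc1 replicate 2), against 1.76 and 1.51 on their slide partners. That grouping was chosen after the values were seen, and each slide gives 1 array against 1. The arrays where RTF1 was dim also had the weaker likely 0 h channel. Its median unprocessed intensity was 105 and 102, against 199 and 169 on their partners. The SD of log2 ratios over all probes was 0.67 and 0.59, against 0.85 and 0.82. Signal strength and RTF1 signal therefore cannot be told apart here. Loss of RTF1 therefore stays open as a hypothesis, untested. Differences in synchrony or yield between cultures were not tested either.

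Mitochondrial probes, outside all comparisons, gave a signal in data that no comparison used: their median log2 ratio, likely 5 h over 0 h, averaged -1.49 over the 4 arrays, with -0.94 and -1.20 on the arrays labelled dmc1 and -2.28 and -1.55 on those labelled rtf1dmc1. Between 36 and 78 of the 136 probes were free of outlier marks. Dye bias is argued against, since the sign of log2(Cy3/Cy5) differed between the slides with a size of at least 0.94 on each array. Loss of signal at the bright end is argued against only as far as brightness was matched. The 5661 nuclear probes taken as bright differed from the mitochondrial median by at least 1.38 on each array. Mitochondrial medians per dye lay from 1.67 to 6.15 log2 units above the array median, so the match on each array may be incomplete. No biological explanation was tested.

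In 3 of the windows named for labelled differences, both arrays of one label were above 0 and both of the other below: CMR2/ARF3 (difference 0.63), CDC73/YLR419W (0.60) and NDD1/NUD1 (0.59). These signs were not tested beyond limma's contrast, which called none.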

How the results depend on the processing

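Probes flagged on no array, medians of probes and the mean over all 4 arrays were alternatives chosen after seeing the data. Of 287 alternative values of 25 named windows, 249 kept direction and side of the threshold, 20 lost the call, 12 gained it and 6 changed sign. The causes of the changes were not tested. Signal over background limits the dim windows. The labels give no numbers that pair arrays, but each slide holds 1 array of each label, so the dye and slide term makes the labelled contrast a comparison within slides. Without that replicate block limma called 339 windows for dmc1 and 1227 for both labels. Promoter windows by coordinates and classes that need an annotation of the same build were not run.

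Normexp background correction used the unprocessed signals, so changes with it may also come from the lost detrending. With it, limma called 0 bins for dmc1, 0 for rtf1dmc1 and 124 for both labels (403 and 1208 at unadjusted p under 0.05 for the labels), and 0 windows for each (132, 509 and 729 at unadjusted p under 0.05). Camera then called 3 lists for dmc1 and 3 for the labelled difference, centromere regions stood at -0.19 against other bins with a labelled difference of -0.15, the chromosome trend was r = -0.55 and HIS4 was -0.061. Regions between divergent genes were 0.23 above other probes. The hotspot median ratio was then 1.31 over 90 regions, and YMR265C/RSN1 was 0.66. With loess the trend was r = -0.53 and arrays of a label correlated at 0.53. With arrays scaled to one spread, 585, 571 and 1376 windows were called for dmc1, rtf1dmc1 and both labels, and the trend was r = -0.18. Without dim probes these were 415 and 346 for dmc1 and rtf1dmc1, with 0 lists for the labelled difference, the difference at chromosome ends was 0.022 and HIS4 was -0.011. With medians of probes HIS4 was -0.044. With only unmarked probes, limma called 15, 0 (785 at unadjusted p under 0.05) and 489 windows for dmc1, rtf1dmc1 and both labels. With unprocessed signals RTF1 stood at -0.996 on the array labelled dmc1 replicate 2 and at -1.19 on that labelled rtf1dmc1 replicate 1.

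Single probes gave 1297 calls for rtf1dmc1 and 3565 for both labels, r = 0.47 between arrays of a label and r = -0.45 between the slides' differences. Bins of 2 kb gave 390, 372 and 1006 calls for dmc1, rtf1dmc1 and both labels, an adjusted p under 0.01 gave 354, 356 and 1042, and windows of at least 3 probes gave 149 for dmc1. With an estimated correlation camera called 0 lists for dmc1, 0 for both labels and 0 for the difference, though that setting could hardly call any. Wider limits put centromere regions at -0.16 and chromosome ends at -0.13 against other bins. Slide 1 alone gave differences of 0.17 near the ribosomal DNA and -0.48 between divergent genes with r = -0.64 for the chromosome trend and a hotspot slope of 0.211, and slide 2 alone gave -0.10, 0.31 and 0.27, with a hotspot slope of 2.69. With the sign turned, differences were 0.072 near centromeres, 0.13 at ends, -0.034 near the ribosomal DNA and 0.082 between divergent genes. The classes then differed from all other bins or probes by 0.29, 0.53, 0.21 and -0.39, and the trend was 0.48.

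Leaving out 1 array assumes that a lone array varies like the others. These fits also lack the dye and slide term, which would leave 3 arrays no residual degree of freedom, so 2 choices change together and the labelled difference is mixed with the slide. That pairing of choices, and RTF1 by unprocessed signals against all windows, were added after seeing the data. Called bins then ranged from 136 to 1336 for dmc1, 257 to 1142 for rtf1dmc1, 1049 to 2908 for both labels and 0 to 27 for the difference. Called windows ranged from 109 to 965, 157 to 861, 748 to 1754 and 0 to 14 in the same order. Without dmc1 replicate 1, 1055 bins and 801 windows were called for rtf1dmc1 and 1094 bins for both labels. Without rtf1dmc1 replicate 1, 1061 bins were called for dmc1, 548 windows for rtf1dmc1 and 1462 windows for both labels, and without rtf1dmc1 replicate 2, 1116 bins and 749 windows for dmc1. Lists ranged from 2 to 5 for dmc1, 4 to 5 for both labels and 0 to 3 for the difference. The chromosome trend ranged from -0.70 to 0.54, the difference between divergent genes from -0.34 to 0.17, near the ribosomal DNA from -0.043 to 0.12, at ends from -0.39 to 0.15 and near centromeres from -0.11 to -0.04. HIS4 ranged from -0.13 (without dmc1 replicate 2) to 0.25. THR4 ranged from -0.44 to 0.079 (without rtf1dmc1 replicate 2), with 0.040 without dmc1 replicate 2.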

Other observations

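The tests of gene span and of position within genes by slide were chosen only after the slide differences were seen. Longer genes differed from shorter ones within each slide. Among 4778 windows of single genes with at least 2 probes well above background, the longest of 3 equal groups (2031 to 14508 bp between outer probes) had a median labelled difference, rtf1dmc1 minus dmc1, of 0.16 on slide 1 and -0.10 on slide 2. DYN1 and TOR2 belong to it. The shortest group (145 to 1193 bp) had -0.22 and 0.17. From shortest to longest group, the slide 1 median ratio ran from 0.27 to -0.18 labelled dmc1 and from 0.07 to -0.004 labelled rtf1dmc1. On slide 2 it ran from 0.22 to -0.14 labelled rtf1dmc1 and from 0.05 to -0.05 labelled dmc1. The arrays where RTF1 was dim thus had the flatter levels, from which an effect of gene length was not told apart. Across these genes, which are not independent replicates, Spearman's rho of the difference with span was 0.35 on slide 1 and -0.26 on slide 2. In the longest group, 996 of 1593 windows were higher by label on slide 1 and 969 were lower on slide 2.

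Within genes divided into 5 equal parts, the slide 1 array labelled dmc1 averaged 0.28 in part 1 and -0.25 in part 4, and the one labelled rtf1dmc1 0.13 and -0.01. On slide 2 the array labelled rtf1dmc1 averaged 0.15 in part 1 and -0.19 in part 4, and the one labelled dmc1 0.07 and -0.04. These are means over probes of single arrays, with no test.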
